A study of Oryza sativa Indica Group with 190 samples.

How the data were processed

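RNA of rice tissues was measured on the Affymetrix rice genome array in 190 arrays from Minghui 63 and Zhenshan 97. Per the labels, the authors computed the deposited values as RMA signal on the log2 scale with the affy package, and gave no versions for either. The values ran from 1.68 to 14.5 with a median of 4.74. Of 57381 probe sets in the file, 187 controls were left out and 57194 were tested. Every sample column was used.

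Technical arrays of a biological sample were averaged first, which left 160 samples in 75 groups. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all samples at once, with 85 residual and 3.85 prior degrees of freedom. A comparison was the mean of the differences in both varieties, tested two-sided with eBayes without trend and adjusted by Benjamini-Hochberg over all probe sets. Callus around Agrobacterium infection was sampled in Zhenshan 97 alone. A probe set passed with an adjusted p under 0.05 and a difference of at least 1. Organ-preferential probe sets had to pass with at least 2 against each of the other 8 classes in each variety. The interaction with variety was tested in the same way. Arrays give no depth, and their number limits precision.

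Gene names came from the reference annotation. Of the probe sets, 22531 were annotated, 22436 of these to 1 gene, and 3191 belonged to genes with a name. The annotation gave no descriptions, so the 30 fixed gene lists were matched to symbols by name before expression by gene was viewed. Lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, and with an estimated correlation and fry as alternatives. Every list was named for chosen comparisons before the data were examined, and was tested there whatever its size, while lists tested elsewhere needed 5 members. The rule for named genes was fixed then too. For the largest rises and falls it took probe sets of 1 named gene that passed with the same sign in both varieties and a mean of at least 8 in the higher group, while members of fixed lists had only to pass. In the infection comparisons all samples of a time had to lie above those of the other. The same sign between the varieties was read as the same sign in every shared tissue. The rule kept the 8 largest rises and 8 largest falls of the 9 main comparisons, 3 of the others, up to 5 for the varieties and each organ class, and 3 or 2 passing members of each fixed list.

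The alternatives used only the compared groups, with and without a block for the replicate number within variety, left out dim probe sets, changed the variance model, recentred or requantiled the arrays, weighted arrays, counted 1 probe set per gene, used the first technical array, and left out each sample in turn. Hormones were also set against the other hormones. After the data were seen, the absence of a minimum difference, the block in the hormone contrast and the removal of samples with a 3′ minus 5′ signal above 2 were added. That signal was the mean over 4 rice control genes. Same-numbered samples were checked for pairing: 84 pairs over 21 comparisons had a median residual correlation of 0.00966, with 24 above 0.1 and 15 below -0.1. In groups of 2 samples both pairs of a variety have the same value by construction. For infection at 6 h, root against shoot and the stem every pair lay above 0.1, which leaves the independence of these samples open.

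The pipeline was tested on simulated data before use. Shared controls were weighed by splitting the untreated samples and by simulation of unchanged groups (20 per pair). Such groups seldom pass, so 0 shared decides nothing. Other splits of the samples, at most 100 per comparison and 30 for the organ classes, were counted with the compared samples alone and variety as a term, which was left out for the split that parts the varieties. Genome positions were not used here.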

Results

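RNA was measured in 39 tissues of Zhenshan 97 and in 36 of these in Minghui 63, both indica rice varieties. The 190 arrays came from 160 biological samples in 75 groups of 1 tissue and 1 variety, of which 65 held 2 and 10 held 3 samples. The groups of 3 were the 3-day and trefoil seedlings and the 3 youngest panicle stages, and each of their samples was read on 2 technical arrays. Array medians lay between 4.62 and 5.04 on the log2 scale, and the number of arrays limits precision. Changes are log2 differences ± SE from the limma model, averaged over both varieties, and a probe set passed at the threshold above. The SE pools variance over all 75 groups and can understate the spread in the compared ones. No background call was used here. Where the mean of the dimmer side less its SD lay below the median signal of 4.74, the difference is one of signals only. Few folds are given at all, and 95 of 374 named genes and comparisons had a dimmer side below this median. A range beside a value holds the differences with each sample left out in turn, and is given where this moved the fold more than 1.5 times.

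Technical arrays of 1 sample correlated with a median r of 0.989 over the probe sets, and biological samples of 1 group with a median of 0.981. The same tissue in the other variety gave 0.966, and another tissue of the same variety gave 0.862. Of the 190 arrays, 162 had an array of the same tissue as the closest one. Stamen had mean correlations to the other tissues of 0.733 in Minghui 63 and 0.799 in Zhenshan 97. Counts of probe sets per comparison ran from 384 for light against dark in the radicle to 14592 for stamen against palea and lemma.

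**Figure D1:**
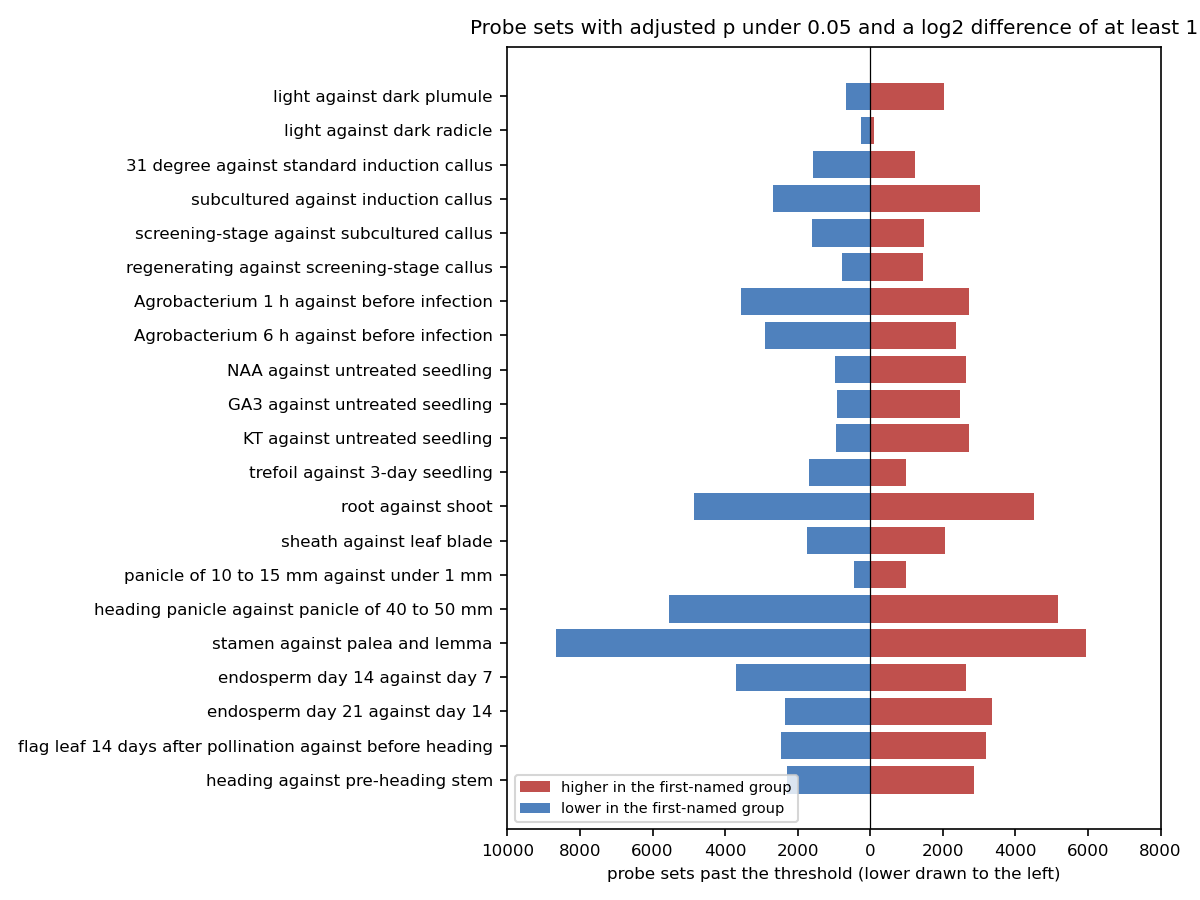
Number of probe sets (horizontal axis) past the threshold in each comparison (vertical axis), higher in the first-named group to the right and lower to the left. Stamen against palea and lemma has the longest bars, and light against dark radicle the shortest.

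Induction of callus at 31 degrees was compared with standard induction, both at 15 days (n = 4 and 4). The alpha-amylase gene AMY1.3 (LOC4345814) rose by 6.80 ± 0.58 (adjusted p = 1.29e-16, range 6.18 to 7.42). The chitinase gene Cht1 (LOC4338719, 4.29 ± 0.62) and the floral MADS gene MADS1 (LOC4332059, 3.92 ± 0.32, range 3.30 to 4.54) also rose. The aquaporin gene PIP2-8 (LOC4334873) fell by 5.59 ± 0.14 (adjusted p = 3.99e-54), and so did ILL3 (LOC4334707, -4.62 ± 0.35) and the expansin gene EXPA1 (LOC4335222, -4.60 ± 0.39). Of 45 heat shock genes 4 rose, 1 fell and 40 did not pass (6 adjusted over the list alone, camera adjusted p = 0.159), and a small heat shock gene, HSP17.9A (LOC4332357, 2.77 ± 0.51), was among the rises. Of 17 defence protein genes 2 rose, 3 fell and 12 did not pass (5 adjusted over the list alone, camera adjusted p = 0.788), with the chitinase gene Cht6 (LOC4329920, -2.30 ± 0.48) among the falls. Of 22 cell cycle and replication genes 0 rose, 1 fell and 21 did not pass (1 adjusted over the list alone, camera adjusted p = 0.788). At 31 degrees 1233 probe sets were higher and 1565 lower, and the differences in both varieties correlated at 0.614. Without a minimum difference 3136 were higher and 3112 lower. The 3′ minus 5′ signal over 4 rice control genes, a sign of RNA quality, was 0.772 ± 0.0471 (SD, n = 4) at 31 degrees and 1.06 ± 0.0613 in standard induction.

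Subcultured callus was compared with induction callus (n = 4 and 4). Storage protein genes were among the largest named falls. The prolamin gene PROLM25 (LOC4342688) fell by 8.84 ± 0.44 (adjusted p = 2.39e-31), and the glutelin gene GLUB-5 (LOC4328968, -7.36 ± 0.62) and ILL3 (-7.49 ± 0.35) fell too. The alpha-amylase gene AMY1.3 rose by 6.95 ± 0.58 (adjusted p = 1.13e-17, range 6.33 to 7.56), as did SPX5 (LOC4333078, 5.16 ± 0.42) and CPDK2 (LOC4333181, 4.65 ± 0.55, range 3.83 to 5.46). Defence protein genes moved both ways: 3 rose, 4 fell and 10 did not pass (9 adjusted over the list alone, camera adjusted p = 0.509). The larger changes were those of chitinase (LOC4351194, 2.87 ± 0.29) and Cht-3 (LOC4342114, -2.93 ± 0.38). Of the glutathione transferases 1 rose, 2 fell and 3 did not pass (3 adjusted over the list alone, camera adjusted p = 0.509), among them GST1 (LOC4334347, 1.76 ± 0.43) and GSTU6 (LOC4349207, -1.68 ± 0.39). In the cell cycle list 1 rose, 1 fell and 20 did not pass (2 adjusted over the list alone, camera adjusted p = 0.178), and the rise was in the cyclin gene CYCA1-4 (LOC4338177, 1.18 ± 0.25). The counts were 3013 probe sets higher and 2686 lower. The 3′ minus 5′ signal was 2.32 ± 0.157 (SD, n = 4) in subcultured and 1.06 ± 0.0613 in induction callus. This was a difference of 1.26, and without samples above 2 no subcultured callus was left.

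Screening-stage callus was compared with subcultured callus (n = 4 and 4). LPR1 rose by 3.69 ± 0.31 (adjusted p = 7.3e-17). So did the isocitrate lyase gene ICL (LOC4343441, 3.69 ± 0.59), of the glyoxylate cycle, and the YABBY family gene YAB5 (LOC4336518, 3.25 ± 0.43). GLU5 (LOC4324643) fell by 3.41 ± 0.33 (adjusted p = 3.52e-14), and so did the lectin gene Agglutinin (LOC4335068, -3.19 ± 0.65). Among defence protein genes 4 rose, 2 fell and 11 did not pass (6 adjusted over the list alone, camera adjusted p = 0.216). The chitinase gene Chia1d (LOC4338720, 2.17 ± 0.32) differed by 4.44 in Minghui 63 and by -0.0895 in Zhenshan 97. Of 6 glutathione transferases 1 rose, 0 fell and 5 did not pass (1 adjusted over the list alone, camera adjusted p = 0.216), the rise being GST1 (1.95 ± 0.43). None of 22 cell cycle and replication genes passed (0 adjusted over the list alone, camera adjusted p = 0.912). The counts were 1481 higher and 1611 lower. The 3′ minus 5′ signal was 1.18 ± 0.36 (SD, n = 4) in screening-stage callus, which makes a difference of -1.14.

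Callus 5 days into regeneration was compared with screening-stage callus (n = 4 and 4). Photosynthesis genes led the rises. The antenna protein gene CAB2R (LOC4324599) rose by 6.74 ± 0.59 (adjusted p = 3.82e-16, range 6.11 to 7.37), and the plastocyanin gene PETE (LOC4339833, 6.35 ± 0.39) and the antenna protein gene RCABP69 (LOC4343583, 5.35 ± 0.52) rose with it. Further rises were those of ADI1 (LOC4344439, 6.43 ± 0.42), the metallothionein gene MT2B (LOC4326409, 6.06 ± 0.46, range 4.99 to 7.14), the sucrose transporter gene SWEET11 (LOC4346153, 5.43 ± 0.63) and the cell wall invertase gene CIN2 (LOC4335790, 4.69 ± 0.41). Of 9 photosystem and antenna genes 8 rose, 0 fell and 1 did not pass (8 adjusted over the list alone, camera adjusted p = 3.26e-22, adjusted p = 0.000106 with an estimated correlation). In chlorophyll synthesis 3 rose, 0 fell and 13 did not pass (5 adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.269 with an estimated correlation), and the rises were CHLH (LOC4332690, 3.25 ± 0.61), PORB (LOC4349004, 2.69 ± 0.38) and LYL1 (LOC4330711, 2.51 ± 0.42). Of 13 cytokinin response genes 6 rose, 0 fell and 7 did not pass (6 adjusted over the list alone, camera adjusted p = 1.35e-05, adjusted p = 0.00305 with an estimated correlation). The response regulator genes RR9 (LOC4349747, 2.54 ± 0.40, range 1.89 to 3.19) and RR4 (LOC4325747, 1.88 ± 0.35) were among them.

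Of 36 auxin response genes in regenerating callus 1 rose, 5 fell and 30 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0666). The rise was in IAA8 (LOC4330571, 2.08 ± 0.27), and IAA26 (LOC4347643, -2.23 ± 0.29) and IAA9 (LOC4331061, -1.74 ± 0.36) were among the falls. Of 21 meristem and branching regulators 5 rose, 4 fell and 12 did not pass (9 adjusted over the list alone, camera adjusted p = 0.48), and FZP (LOC4344233, -2.21 ± 0.24) and WOX10 (LOC4345042, -1.93 ± 0.20) were lower. ACC2 (LOC4336750) fell by 3.73 ± 0.56 (adjusted p = 2.12e-07). The jasmonate repressor gene JAZ11 (LOC4331833, -3.32 ± 0.61), the laccase gene LAC24 (LOC4351915, -3.21 ± 0.58, range -4.01 to -2.40) and the SPX genes SPX2 (LOC4328654, -2.89 ± 0.43) and SPX5 (-2.73 ± 0.42) fell as well. None of 22 cell cycle and replication genes passed (0 adjusted over the list alone, camera adjusted p = 0.214). Of LEA and dehydrin genes 0 rose, 1 fell and 8 did not pass (1 adjusted over the list alone, camera adjusted p = 0.214). The counts were 1465 higher and 786 lower.

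Callus of Zhenshan 97 was sampled just before and 1 h and 6 h after infection with Agrobacterium, the bacterium used for gene transfer (n = 2 per time). At 1 h the jasmonate repressor gene JAZ13 (LOC4348531) rose by 6.54 ± 1.01 (adjusted p = 4.21e-07, range 5.89 to 7.20). The repressor gene JAZ9 (LOC4331832, 5.38 ± 1.02), the transcription factor gene WRKY24 (LOC4327518, 5.60 ± 0.77), PHT3 (LOC4347747, 6.83 ± 0.85) and RFS (LOC4325200, 6.66 ± 0.83) rose too. Falls included SPX2 (-3.0 ± 0.61) and GLU14 (LOC4328141, -2.88 ± 0.44). Of 32 jasmonate pathway genes 15 rose, 0 fell and 17 did not pass (15 adjusted over the list alone, camera adjusted p = 3.51e-08, adjusted p = 0.0333 with an estimated correlation). Of 6 WRKY factors 3 rose, 0 fell and 3 did not pass (3 adjusted over the list alone, camera adjusted p = 0.00358, adjusted p = 0.0838 with an estimated correlation). In the defence protein list 6 rose, 0 fell and 11 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00358, adjusted p = 0.0838 with an estimated correlation), with the chitinase genes Cht6 (3.53 ± 0.68) and Cht2 (LOC4349267, 3.42 ± 0.77). Of 45 heat shock genes 14 rose, 1 fell and 30 did not pass (19 adjusted over the list alone, camera adjusted p = 3.15e-05, adjusted p = 0.105 with an estimated correlation), and HSP18.1 (LOC4332361, 4.53 ± 1.11) was one that rose. None of 16 diterpenoid phytoalexin genes passed (0 adjusted over the list alone, camera adjusted p = 0.185). For glutathione transferases 1 rose, 0 fell and 5 did not pass (1 adjusted over the list alone, camera adjusted p = 0.533), the rise being GSTF1 (LOC4325710, 3.33 ± 0.63). At 1 h, 2716 probe sets were higher and 3552 lower.

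At 6 h after infection PHT3 rose by 7.70 ± 0.85 (adjusted p = 1.33e-11). Genes of the diterpenoid phytoalexins, antimicrobial compounds of rice, were higher too, among them KSL4 (LOC4335094, 4.67 ± 0.76), CYP99A2 (LOC4335096, 4.38 ± 0.85) and CPS4 (LOC4335090, 3.96 ± 0.85). Further rises were the dehydrin gene RAB16C (LOC4350452, 5.71 ± 0.91), mdr17 (LOC4324720, 5.58 ± 0.60) and PIN5 (LOC4327533, 5.22 ± 0.62, range 4.59 to 5.85). The aquaporin gene TIP2-2 (LOC4340941) fell by 4.11 ± 0.44 (adjusted p = 4.7e-12), and so did the aquaporin genes PIP2-6 (LOC4335226, -3.83 ± 0.44) and TIP3 (LOC4348981, -3.68 ± 0.76, range -4.63 to -2.74). The expansin gene EXPB7 (LOC4331300, -3.52 ± 0.64) and the catalase gene CAT-A (LOC4328073, -3.2 ± 0.62) were lower as well. Of the 16 phytoalexin genes 6 rose, 0 fell and 10 did not pass (7 adjusted over the list alone, camera adjusted p = 0.000195, adjusted p = 0.17 with an estimated correlation). In the jasmonate pathway 17 rose, 0 fell and 15 did not pass (18 adjusted over the list alone, camera adjusted p = 5.43e-09, adjusted p = 0.0243 with an estimated correlation), with JAZ9 (5.13 ± 1.02), JAZ13 (5.02 ± 1.01, range 4.36 to 5.67) and JAZ5 (LOC4335698, 4.61 ± 0.75).

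At 6 h, among the WRKY factors, 3 rose, 0 fell and 3 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0316, adjusted p = 0.17 with an estimated correlation), and WRKY24 (4.66 ± 0.77) changed most. Of the defence protein genes 4 rose, 0 fell and 13 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.17 with an estimated correlation). These included the chitinase gene Cht2 (3.87 ± 0.77) and the phenylalanine ammonia-lyase gene PAL06 (LOC4330040, 2.79 ± 0.57). Of the heat shock genes at this time, 3 rose, 0 fell and 42 did not pass (6 adjusted over the list alone, camera adjusted p = 0.168), and the heat shock factor gene HSFA4D (LOC4339409, 3.76 ± 0.60) changed most. In the glutathione transferase list 1 rose, 0 fell and 5 did not pass (3 adjusted over the list alone, camera adjusted p = 0.813). Of 23 cytosolic ribosomal protein genes 0 rose, 1 fell and 22 did not pass (1 adjusted over the list alone, camera adjusted p = 0.619). At 6 h, 2351 probe sets were higher and 2895 lower, a total of 5246. Both times share the 2 samples taken before infection, which alone gave differences correlated at 0.5 in 20 simulations, against 0.823 here. At both, 1673 probe sets were higher and 1784 lower, against 112 and 180 for independent lists, and the shared samples' part was not tested.

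Plumules, the embryonic shoots, were grown in light or in darkness (n = 4 and 4). The antenna protein gene CAB2R rose by 6.69 ± 0.59 (adjusted p = 1.18e-15) in light. With it rose the antenna protein genes RCABP89 (LOC4333359, 5.93 ± 0.70, range 5.32 to 6.54) and RCABP69 (5.48 ± 0.52, range 4.84 to 6.13), the photosystem I gene PSAH (LOC4339593, 3.96 ± 0.41) and the oxygen-evolving complex gene OEE3 (LOC4343515, 3.71 ± 0.39, range 2.81 to 4.60). The germin-like protein gene GER2 (LOC4344839, 5.52 ± 0.56, range 4.11 to 6.92) and the nicotianamine synthase gene NAS3 (LOC4344361, 3.87 ± 0.51, range 3.10 to 4.64) rose too. PM1 (LOC4338635) fell by 3.84 ± 0.59 (adjusted p = 4.57e-07, range -4.52 to -3.16), and so did the homeobox gene OSH1 (LOC4333973, -3.51 ± 0.45) and the lipid transfer protein gene LTP-2 (LOC4331362, -3.45 ± 0.48). Of 9 photosystem and antenna genes 8 rose, 0 fell and 1 did not pass (8 adjusted over the list alone, camera adjusted p = 2.27e-18, adjusted p = 0.00047 with an estimated correlation). In the Calvin cycle 3 rose, 0 fell and 1 did not pass (3 adjusted over the list alone, camera adjusted p = 4.56e-05, adjusted p = 0.00659 with an estimated correlation), and the rises were RCAA1 (LOC4351224, 3.25 ± 0.44, range 2.52 to 3.97), ALDP (LOC4349897, 2.91 ± 0.44) and RBCS (LOC4351966, 2.81 ± 0.41). Of 16 chlorophyll synthesis genes 8 rose, 0 fell and 8 did not pass (9 adjusted over the list alone, camera adjusted p = 4.08e-09, adjusted p = 0.0025 with an estimated correlation), with CHLH (3.21 ± 0.61) and PORB (2.74 ± 0.38).

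Of 7 circadian clock genes in plumules 3 rose, 0 fell and 4 did not pass (3 adjusted over the list alone, camera adjusted p = 0.00717, adjusted p = 0.0475 with an estimated correlation), with GI (LOC4325329, 2.75 ± 0.43) and PRR73 (LOC4332464, 2.39 ± 0.33). Hypoxia and fermentation genes pointed down, as 0 rose, 3 fell and 3 did not pass (3 adjusted over the list alone, camera adjusted p = 0.00151, adjusted p = 0.0875 with an estimated correlation). The falls were NSHB2 (-3.62 ± 0.77, range -5.28 to -1.97), NSHB1 (-3.32 ± 0.69, range -4.94 to -1.69) and Adh2 (LOC4350054, -2.49 ± 0.52, range -3.44 to -1.54). None of these passed with only the plumule groups in the fit (adjusted p = 0.17, 0.198 and 0.109), nor without dark-grown Zhenshan 97 replicate 2 (adjusted p = 0.184, 0.18 and 0.0989). Of 29 expansin genes 2 rose, 0 fell and 27 did not pass (4 adjusted over the list alone, camera adjusted p = 0.54), and EXPB2 (LOC4349348, 3.62 ± 0.39) rose. The counts were 2038 higher and 681 lower, and differences in both varieties correlated at 0.691. In light the 3′ minus 5′ signal was 1.14 ± 0.205 (SD, n = 4), and in darkness 0.903 ± 0.12.

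Radicles, the embryonic roots, were grown in light or in darkness as well (n = 4 and 4). The iron transporter gene IRT1 (LOC4333669) rose by 2.49 ± 0.43 (adjusted p = 6.11e-05), with 4.32 in Minghui 63 and 0.67 in Zhenshan 97. The clock gene PRR73 (1.76 ± 0.33) rose, and the lipid transfer protein gene LTP2-B (LOC4351317, -2.31 ± 0.39) fell. None of 9 photosystem and antenna genes passed (0 adjusted over the list alone, camera adjusted p = 0.0386, adjusted p = 0.463 with an estimated correlation), nor any of 4 Calvin cycle genes (0 adjusted over the list alone, camera adjusted p = 0.283). The same held for 16 chlorophyll synthesis genes (0 adjusted over the list alone, camera adjusted p = 0.203). Of the clock genes 1 rose, 0 fell and 6 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0386, adjusted p = 0.288 with an estimated correlation). Of the expansin genes 0 rose, 1 fell and 28 did not pass (1 adjusted over the list alone, camera adjusted p = 0.265). The counts were 116 higher and 268 lower. With only the radicle groups in the fit the total of 384 became 64, with a replicate block as well 6, and without light-grown Zhenshan 97 replicate 2 it was 244. IRT1 (adjusted p = 0.0596), PRR73 (adjusted p = 0.0627) and LTP2-B (adjusted p = 0.211) did not pass with only the radicle groups. The difference in light response between plumule and radicle was tested itself. It passed in 1444 probe sets with the higher value in plumule and 242 with the lower. This total of 1686 was 1107 without dark-grown plumule Zhenshan 97 replicate 2.

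Trefoil seedlings received auxin (NAA), gibberellin (GA3) or cytokinin (KT), each as a mix of samples taken after 5, 15, 30 and 60 min. They were compared with untreated trefoil seedlings (n = 4 and 6). With NAA the auxin-conjugating enzyme gene GH3.2 (LOC4326893) rose by 2.27 ± 0.44 (4.82-fold, adjusted p = 2.26e-05), and so did its relative GH3.4 (LOC4339234, 1.72 ± 0.44) and the early auxin gene IAA20 (LOC4340245, 1.74 ± 0.34). Of 36 auxin response genes 4 rose, 0 fell and 32 did not pass (5 adjusted over the list alone, camera adjusted p = 0.254). Other rises were MRL7 (LOC4327529, 2.49 ± 0.39), GYRA (LOC4334546, 2.11 ± 0.32), EGY1 (LOC4334387, 1.89 ± 0.28) and the chlorophyll synthase gene CHLG (LOC4338498, 1.86 ± 0.22). The dehydrin gene RAB16D (LOC4350451) fell by 3.25 ± 0.58 (adjusted p = 6.43e-06), and so did the MADS gene MADS18 (LOC4343851, -2.83 ± 0.29). The counts were 2624 higher and 969 lower, but 8924 and 11771 without a minimum difference.

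With GA3 the nicotianamine synthase gene NAS2 (LOC4332607) rose by 3.18 ± 0.56 (adjusted p = 5.87e-06, range 1.64 to 4.72), which did not pass with only these groups and a replicate block (adjusted p = 0.0951). MRL7 (2.54 ± 0.39), which did not pass there either (adjusted p = 0.0509), and BGLU3 (LOC4327593, 2.07 ± 0.38) rose too. The falls were led by RAB16D (-3.09 ± 0.58), MADS18 (-2.66 ± 0.29) and Cht1 (-2.62 ± 0.57). None of 7 gibberellin pathway genes passed (0 adjusted over the list alone, camera adjusted p = 0.133, fry adjusted p = 0.189). Among auxin response genes 3 rose, 1 fell and 32 did not pass (4 adjusted over the list alone, camera adjusted p = 0.635). The counts were 2470 higher and 929 lower, but 8568 and 10991 without a minimum difference. The 3′ minus 5′ signal was 1.38 ± 0.75 (SD, n = 4) with GA3, 1.25 ± 0.0629 with NAA and 0.851 ± 0.0857 (n = 6) in untreated seedlings.

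With KT the dehydrin gene RAB16D fell by 3.85 ± 0.58 (adjusted p = 1.53e-07), as did Cht1 (-3.19 ± 0.57) and MADS18 (-3.07 ± 0.29). The rises were led by NAS2 (2.97 ± 0.56, range 1.79 to 4.15), MRL7 (2.61 ± 0.39) and the phosphate transporter gene PT1 (LOC4331637, 2.29 ± 0.37, range 1.56 to 3.03). None of 13 cytokinin response genes passed (0 adjusted over the list alone, camera adjusted p = 0.962). For KT 2707 probe sets were higher and 945 lower. Of these 74.1% were higher, and 62.1% after quantile normalization of the compared arrays alone. Replicate 2 of Minghui 63 with KT had the highest median (5.04) and mean (5.653) of all arrays, and leaving out each sample in turn took the total of 3652 to between 3132 and 4413. With KT the 3′ minus 5′ signal was 1.04 ± 0.113 (SD, n = 4).

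Other lists were tested for each hormone. In the jasmonate pathway with NAA 1 rose, 2 fell and 29 did not pass (1 adjusted over the list alone, camera adjusted p = 0.0211, adjusted p = 0.454 with an estimated correlation), with GA3 1 rose, 1 fell and 30 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0237, adjusted p = 0.471 with an estimated correlation). In the jasmonate list with KT, 2 rose, 2 fell and 28 did not pass (4 adjusted over the list alone, camera adjusted p = 0.376). In the auxin list with KT 1 rose, 1 fell and 34 did not pass (1 adjusted over the list alone, camera adjusted p = 0.962). No cytokinin response gene passed with NAA (0 adjusted over the list alone, camera adjusted p = 0.254) or GA3 (0 adjusted over the list alone, camera adjusted p = 0.219), and no gibberellin pathway gene with NAA (0 adjusted over the list alone, camera adjusted p = 0.254) or KT (0 adjusted over the list alone, camera adjusted p = 0.397). Of 7 clock genes with NAA 1 rose, 0 fell and 6 did not pass (1 adjusted over the list alone, camera adjusted p = 0.802). In the clock list with KT, 1 rose, 0 fell and 6 did not pass (1 adjusted over the list alone, camera adjusted p = 0.962), and with GA3 none passed (0 adjusted over the list alone, camera adjusted p = 0.635). None of 6 WRKY factors passed with NAA (0 adjusted over the list alone, camera adjusted p = 0.254), GA3 (0 adjusted over the list alone, camera adjusted p = 0.426) or KT (0 adjusted over the list alone, camera adjusted p = 0.962).

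Of 4703 probe sets that passed with any hormone, 1888 were higher and 620 lower with each of the 3. NAA and GA3 shared 2067 higher and 740 lower, against 113 and 15.7 for independent lists, and with the control samples split between them 1598 and 517. That split addresses only the shared control. All 12 treated samples correlated most with the same-numbered sample of another hormone (0.9841 to 0.9953, against 0.9685 to 0.992 within their own group). With split controls and different sample numbers for the 2 hormones, a test chosen after this was seen, NAA and GA3 shared 1463 or 1590 probe sets of 2807. The untreated seedlings belong to the tissues read on technical arrays and the treated ones do not, and the labels name no batch. The shared probe sets moved the same way, by a median of 0.51, between panicles of 40 to 50 mm and of 10 to 15 mm, which differ in that respect too, and by 0.99 between light-grown plumules and 3-day seedlings.

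Set against the mean of the other hormones, with the replicate number as a block, 6 probe sets passed for NAA, 0 for GA3 and 24 for KT (1, 0 and 3 without the block) in limma, an alternative whose block was added after the data were seen. For GA3 3036 probe sets had an unadjusted p under 0.05 with the block and 1001 without it, and no other tool was run. IAA20 stood 1.51 ± 0.14 above the other hormones with NAA (adjusted p = 0.0147). With KT the cytokinin response regulator gene RR9 stood 1.14 ± 0.10 above them (adjusted p = 0.00445), and so did the jasmonate repressor genes JAZ13, by 1.66 ± 0.11 (adjusted p = 0.00133), and JAZ10, by 1.10 ± 0.15 (adjusted p = 0.042). These genes were picked from that test after its values were seen. Without the block none of the 4 passed (adjusted p = 0.186 for IAA20, 0.621 for JAZ13, 0.43 for RR9 and 0.7 for JAZ10). Of 43 pairs of gene and hormone that the rule for named genes took from the comparisons with untreated seedlings, 2 passed with the block, IAA20 with NAA and JAZ13 with KT. There MRL7 with NAA (-0.089) and GA3 (-0.014), and RAB16D with NAA (0.22) and GA3 (0.46), took the opposite sign.

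**Figure D2:**
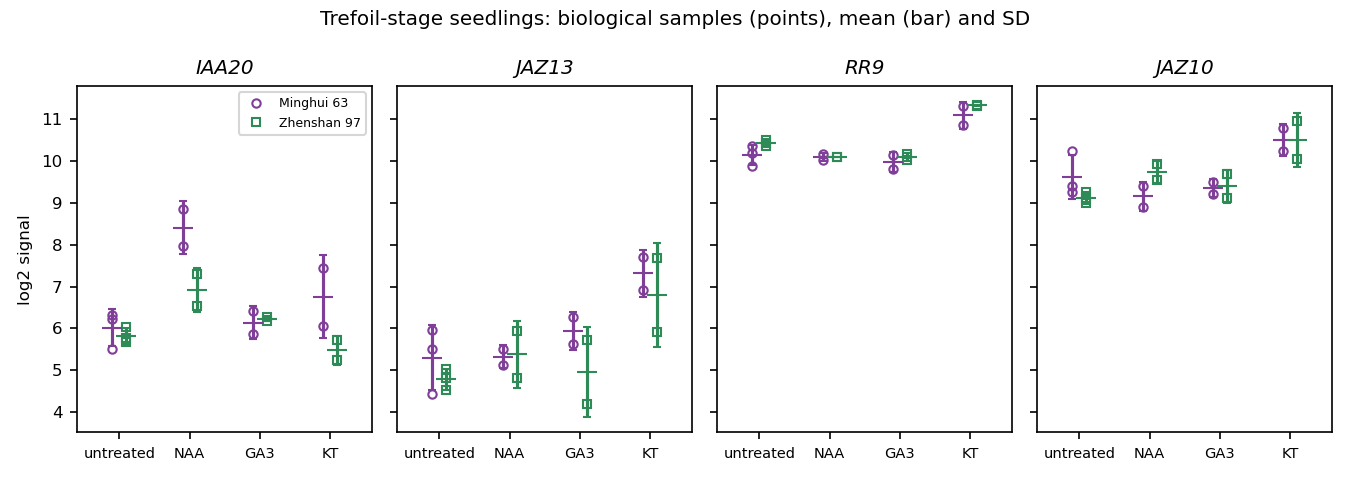
Log2 signal (vertical axis) of IAA20, JAZ13, RR9 and JAZ10 in untreated trefoil seedlings and with NAA, GA3 and KT (horizontal axis), with points for samples and mean and SD by variety. IAA20 has its highest group means with NAA, and the other genes with KT.

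Trefoil seedlings were also compared with seedlings 3 days after sowing (n = 6 and 6). The ammonium transporter gene AMT1-2 (LOC4330008) rose by 4.37 ± 0.32 (adjusted p = 3.73e-20), and so did the MADS gene MADS18 (3.86 ± 0.26) and the potassium transporter gene HAK27 (LOC4333296, 3.53 ± 0.35). The small heat shock gene HSP16.9A (LOC4325697) fell by 6.50 ± 0.49 (adjusted p = 3.3e-19). Lower as well were the heat shock gene HSP23.2 (LOC4335956, -5.26 ± 0.56) and the cold response factor gene CBF3 (LOC4347620, -5.11 ± 0.57, range -5.71 to -4.80). Of 5 alpha-amylase genes 0 rose, 2 fell and 3 did not pass (2 adjusted over the list alone, camera adjusted p = 0.207). The larger fall, AMY1.1 (LOC4330832, -3.49 ± 0.78, range -4.62 to -1.99), did not pass with only the seedling groups in the fit (adjusted p = 0.138). None passed of 9 photosystem and antenna genes (0 adjusted over the list alone, camera adjusted p = 0.207) or 10 seed storage protein genes (0 adjusted over the list alone, camera adjusted p = 0.207). Nor did any of 22 cell cycle and replication genes (0 adjusted over the list alone, camera adjusted p = 0.867). In trefoil seedlings 973 probe sets were higher and 1701 lower, but without a minimum difference 8566 and 5146. Their 3′ minus 5′ signal was 0.851 ± 0.0857, and that of 3-day seedlings 1.11 ± 0.123 (SD, n = 6).

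Root was compared with shoot in seedlings with 2 tillers (n = 4 and 4). The nicotianamine synthase gene NAS1 (LOC4332608) rose by 7.84 ± 0.74 (adjusted p = 3.87e-16, range 7.15 to 8.53), and so did its relative NAS2 (7.05 ± 0.62, range 6.28 to 7.82). Also higher in root were the silicon efflux transporter gene Lsi2 (LOC4331328, 6.78 ± 0.35), the phosphate transporter gene PT1 (6.71 ± 0.40), the aluminium transporter gene Nrat1 (LOC4328200, 6.43 ± 0.37), the metallothionein gene MT4C (LOC4352582, 7.72 ± 0.46) and the aquaporin gene TIP2 (LOC4330207, 7.16 ± 0.47, range 6.21 to 8.11). LTP2-B fell by 8.57 ± 0.39 (adjusted p = 4.07e-35) in root. Lower there too were the aquaporin gene PIP2-7 (LOC4347729, -8.03 ± 0.34), the Rubisco activase gene RCAA1 (-7.94 ± 0.44), LFNR1 (-7.91 ± 0.33) and the glycine decarboxylase gene GDCSH (LOC4349114, -7.67 ± 0.38). Of 16 nutrient transport genes 11 rose, 1 fell and 4 did not pass (12 adjusted over the list alone, camera adjusted p = 6.53e-07, adjusted p = 0.012 with an estimated correlation). Among 9 photosystem and antenna genes 0 rose, 9 fell and 0 did not pass (9 adjusted over the list alone, camera adjusted p = 4.89e-09, adjusted p = 0.012 with an estimated correlation), for example PSB28 (LOC4326537, -6.61 ± 0.34).

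Secondary wall genes split between root and shoot, as 7 rose, 5 fell and 12 did not pass (12 adjusted over the list alone, camera adjusted p = 0.68). The cinnamyl alcohol dehydrogenase family gene CAD8A (LOC4346988, 5.03 ± 0.35) was higher in root, and its relative CAD3 (LOC4348690, -5.26 ± 0.27) and the laccase gene LAC20 (LOC4351006, -5.03 ± 0.32) in shoot. Of 17 defence protein genes 7 rose, 4 fell and 6 did not pass (11 adjusted over the list alone, camera adjusted p = 0.366), such as Cht10 (LOC4325148, 3.24 ± 0.32) and PBZ1 (LOC4352491, -3.64 ± 0.51). In root 4498 probe sets were higher and 4864 lower, but without a minimum difference 10549 and 7336. In root the 3′ minus 5′ signal was 0.908 ± 0.0775, and in shoot 1.66 ± 1.02 (SD, n = 4).

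Sheath was compared with leaf blade at 2 stages of panicle growth (n = 8 and 8). NH5 (LOC4351457) rose by 5.12 ± 0.25 (adjusted p = 5.39e-32) in sheath, and so did the auxin response gene IAA30 (LOC4352721, 4.11 ± 0.24) and G1L2 (LOC4341811, 3.86 ± 0.21). Blade had more of CPS2 (LOC9266189, -3.10 ± 0.48, range -3.88 to -2.31) and CYP701A8 (LOC4341343, -2.66 ± 0.38), both of diterpenoid synthesis, and of the potassium transporter gene HAK27 (-2.97 ± 0.30). Of 24 secondary wall genes 9 rose, 0 fell and 15 did not pass (9 adjusted over the list alone, camera adjusted p = 0.000245, adjusted p = 0.0465 with an estimated correlation), led by the cellulose synthase gene CESA4 (LOC4324625, 2.62 ± 0.29, range 2.00 to 3.25) and by BC1 (LOC4333114, 2.44 ± 0.30). Among expansin genes 10 rose, 0 fell and 19 did not pass (10 adjusted over the list alone, camera adjusted p = 0.000245, adjusted p = 0.0465 with an estimated correlation), with EXPB11 (LOC4330213, 3.11 ± 0.34) and EXPB7 (2.93 ± 0.32). None passed of 9 photosystem and antenna genes (0 adjusted over the list alone, camera adjusted p = 0.315) or 4 Calvin cycle genes (0 adjusted over the list alone, camera adjusted p = 0.544). In sheath 2059 probe sets were higher and 1756 lower, but without a minimum difference 5715 and 7857.

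The flag leaf 14 days after pollination was compared with the flag leaf before heading (n = 4 and 4). The jasmonate repressor gene JAZ13 rose by 6.47 ± 0.71 (adjusted p = 1.98e-12), and so did the repressor genes JAZ10 (LOC4331834, 5.69 ± 0.52, range 5.09 to 6.29) and JAZ9 (5.54 ± 0.72, range 4.76 to 6.32). Further rises were ABCG48 (LOC4350807, 7.03 ± 0.38), AT5 (LOC4338283, 6.12 ± 0.54, range 5.27 to 6.98), the MADS gene MADS5 (LOC4340218, 5.77 ± 0.29) and the cold response factor gene DREB1G (LOC4330306, 5.51 ± 0.85, range 4.41 to 6.60). The aquaporin gene TIP2-2 fell by 3.74 ± 0.31 (adjusted p = 8.28e-18). With it fell the sugar transporter gene SWEET1A (LOC4324848, -3.72 ± 0.29), the chalcone synthase gene CHS (LOC4350636, -3.72 ± 0.45), the cellulose synthase gene CESA8 (LOC4342699, -3.66 ± 0.24) and the protochlorophyllide reductase gene PORA (LOC4337415, -3.31 ± 0.60). Of 8 senescence and chlorophyll breakdown genes 3 rose, 0 fell and 5 did not pass (3 adjusted over the list alone, camera adjusted p = 0.174), with the stay-green gene SGR (LOC4347672, 2.19 ± 0.37).

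Of the photosystem and antenna genes in the flag leaf 0 rose, 6 fell and 3 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00657, adjusted p = 0.231 with an estimated correlation), with RCABP69 (-2.90 ± 0.52). In the Calvin cycle list 0 rose, 3 fell and 1 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0428, adjusted p = 0.231 with an estimated correlation), with ALDP (-2.39 ± 0.44) and RBCS (-1.83 ± 0.41). In the defence protein list 7 rose, 0 fell and 10 did not pass (7 adjusted over the list alone, camera adjusted p = 0.0428, adjusted p = 0.231 with an estimated correlation), with the chitinase gene Cht6 (3.54 ± 0.48). Of the clock genes there 0 rose, 2 fell and 5 did not pass (2 adjusted over the list alone, camera adjusted p = 0.161), among them PRR37 (LOC4344399, -1.28 ± 0.33). The counts were 3181 higher and 2454 lower. This total of 5635 was 3290 with only these groups and a replicate block.

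The stem at heading was compared with the stem before heading (n = 4 and 4). The germin-like protein gene GER5 (LOC4345763) rose by 7.02 ± 0.55 (adjusted p = 9.79e-19), and so did its relative GER8 (LOC4325743, 4.39 ± 0.56, range 3.31 to 5.46) and the MADS gene MADS34 (LOC4334141, 5.68 ± 0.17). The small heat shock gene HSP26.7 (LOC4332237) fell by 5.35 ± 0.63 (adjusted p = 4.88e-11), as did HSP16.9A (-4.19 ± 0.61) and the nicotianamine synthase gene NAS3 (-4.63 ± 0.51, range -5.40 to -3.87). Of the secondary wall genes 9 rose, 1 fell and 14 did not pass (11 adjusted over the list alone, camera adjusted p = 0.00121, adjusted p = 0.0843 with an estimated correlation). The laccase gene LAC4 (LOC4327500, 3.2 ± 0.48, range 2.05 to 4.34) did not pass with only the stem groups in the fit (adjusted p = 0.0627). In the expansin list 9 rose, 0 fell and 20 did not pass (9 adjusted over the list alone, camera adjusted p = 0.000101, adjusted p = 0.0587 with an estimated correlation), with EXPA1 (3.09 ± 0.39) and EXPB7 (2.83 ± 0.46). Cell cycle and replication genes had calls as well: 5 rose, 1 fell and 16 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00257, adjusted p = 0.306 with an estimated correlation). The cyclin gene CYCB1-1 (LOC4327547, 2.14 ± 0.28) differed by 3.85 in Minghui 63 and 0.44 in Zhenshan 97. Among photosystem and antenna genes 6 rose, 0 fell and 3 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00257, adjusted p = 0.22 with an estimated correlation), with PSAH (2.57 ± 0.41). The counts were 2853 higher and 2283 lower, but 5032 and 6166 without a minimum difference. The 3′ minus 5′ signal was 0.757 ± 0.135 at heading and 1.36 ± 0.429 (SD, n = 4) before.

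Panicles of 10 to 15 mm were compared with panicles under 1 mm (n = 6 and 6). The MADS gene MADS7 (LOC4346134) rose by 4.90 ± 0.34 (adjusted p = 7.01e-22), and so did the MADS genes MADS58 (LOC4338067, 4.48 ± 0.32) and MADS8 (LOC4347517, 4.12 ± 0.30), all of them known from flower organs. APO2 (LOC4336857) fell by 3.12 ± 0.14 (adjusted p = 1.96e-33), and so did LAX1 (LOC4327431, -2.99 ± 0.17) and SPL14 (LOC4345998, -2.08 ± 0.19), known regulators of panicle branching. Another MADS gene, MADS55 (LOC4340495, -4.14 ± 0.26), and GATA15 (-2.89 ± 0.17) fell too. Further rises were the antenna protein gene CAB2R (4.41 ± 0.48), FIL1 (LOC4342449, 3.80 ± 0.42), CML27 (LOC4332731, 3.57 ± 0.32) and the expansin gene EXPA6 (LOC4332763, 2.86 ± 0.25). Of 17 floral MADS genes 10 rose, 1 fell and 6 did not pass (11 adjusted over the list alone, camera adjusted p = 7.72e-16, adjusted p = 4.1e-05 with an estimated correlation). Of 21 meristem and branching regulators 0 rose, 4 fell and 17 did not pass (4 adjusted over the list alone, camera adjusted p = 1.31e-05, adjusted p = 0.000634 with an estimated correlation). In the tapetum and pollen wall list, of genes that act in the anther, 2 rose, 0 fell and 6 did not pass (2 adjusted over the list alone, camera adjusted p = 1.31e-05, adjusted p = 0.000728 with an estimated correlation), with BHLH142 (LOC4325164, 2.14 ± 0.12). Of 11 meiosis genes 1 rose, 0 fell and 10 did not pass (1 adjusted over the list alone, camera adjusted p = 0.754), the rise being the germ cell Argonaute gene MEL1 (LOC4334449, 2.5 ± 0.20). None of 22 cell cycle and replication genes passed (0 adjusted over the list alone, camera adjusted p = 0.123). The counts were 987 higher and 458 lower.

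**Figure D3:**
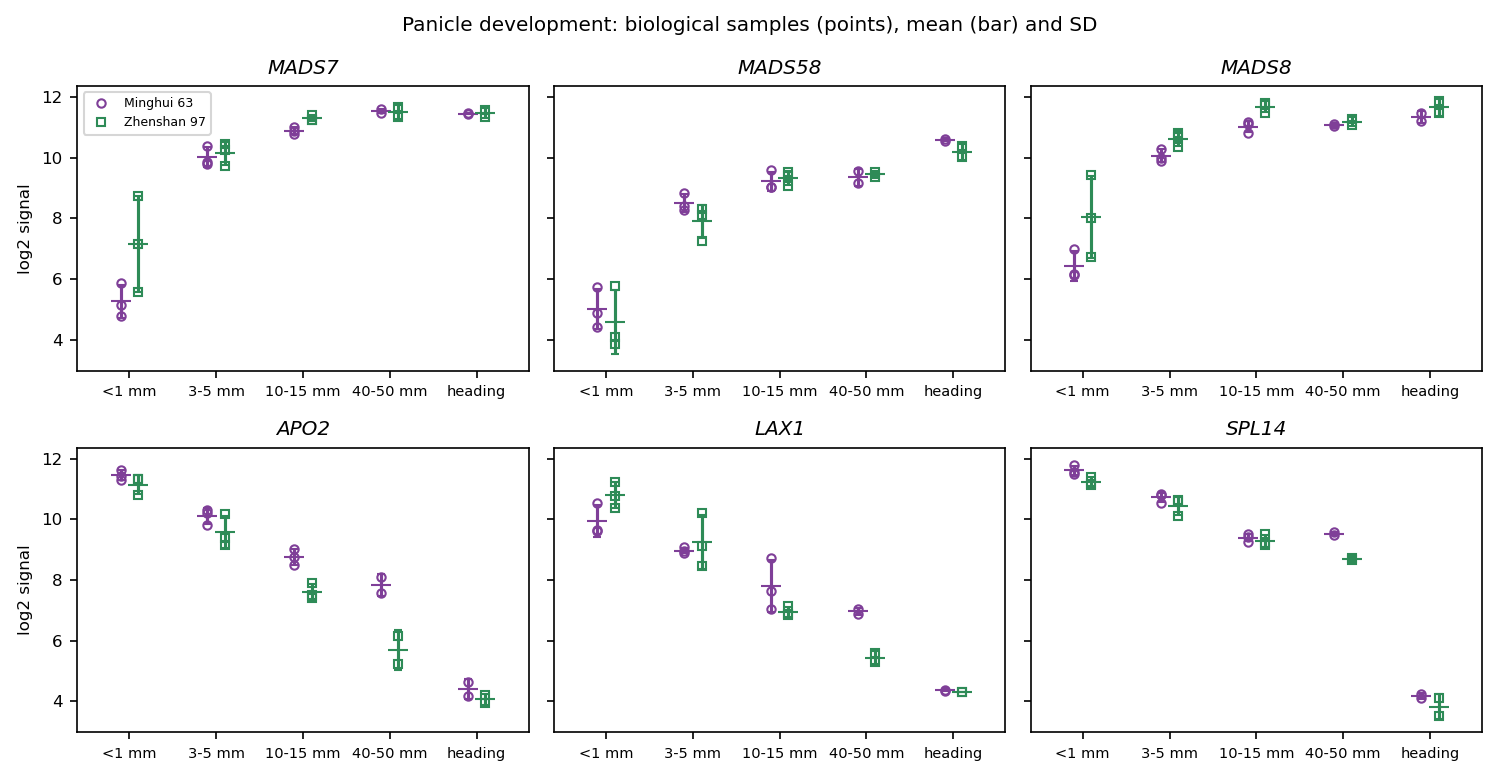
Log2 signal (vertical axis) of 3 MADS genes and 3 meristem regulators over 5 panicle stages (horizontal axis), with points for samples and mean and SD by variety. MADS7, MADS58 and MADS8 are higher and APO2, LAX1 and SPL14 lower at 10 to 15 mm than under 1 mm.

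The heading panicle was compared with the panicle of 40 to 50 mm (n = 4 and 4). The expansin gene EXPB10 (LOC4331325) rose by 9.35 ± 0.14 (adjusted p = 6.9e-72), and so did its relative EXPB9 (LOC4349301, 8.97 ± 0.39) and the actin depolymerizing factor gene ADF-9 (LOC4343240, 8.90 ± 0.34). The germin-like protein gene GER5 fell by 6.68 ± 0.55 (adjusted p = 4.78e-19), and so did BCL1 (LOC4346166, -6.28 ± 0.38) and the cyclin gene CYCB2 (LOC4342121, -5.31 ± 0.30). Of 22 cell cycle and replication genes 0 rose, 22 fell and 0 did not pass (22 adjusted over the list alone, camera adjusted p = 6.09e-10, adjusted p = 0.0507 with an estimated correlation). Of 11 meiosis genes 0 rose, 10 fell and 1 did not pass (10 adjusted over the list alone, camera adjusted p = 1.54e-05, adjusted p = 0.00981 with an estimated correlation), with MEL1 (-3.50 ± 0.25) and the mismatch repair family gene MSH5 (LOC4339215, -2.68 ± 0.23). Of 2 genes of mature pollen families 2 rose, 0 fell and 0 did not pass (2 adjusted over the list alone, camera adjusted p = 6.38e-06, adjusted p = 0.000298 with an estimated correlation). In the tapetum and pollen wall list 2 rose, 3 fell and 3 did not pass (5 adjusted over the list alone, camera adjusted p = 0.617), for example RTS (LOC4326940, 8.56 ± 0.34, range 7.73 to 9.40) and BHLH142 (-3.31 ± 0.15). In the photosystem and antenna list 7 rose, 0 fell and 2 did not pass (9 adjusted over the list alone, camera adjusted p = 0.000946, adjusted p = 0.153 with an estimated correlation), with petC (LOC4343570, 3.37 ± 0.32). The counts were 5180 higher and 5558 lower.

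Stamen was compared with palea and lemma, the outer floral organs, just before heading (n = 4 and 4). The MADS gene MADS27 (LOC4329771) rose by 6.31 ± 0.31 (adjusted p = 7.66e-34) in stamen, which also had more of SPPL3 (LOC4324348, 6.10 ± 0.24), the tapetum gene RTS (5.95 ± 0.34, range 4.86 to 7.05), LFL1 (LOC4325939, 5.84 ± 0.31) and IMCE (LOC4339700, 5.77 ± 0.20). FIL1 fell by 8.89 ± 0.51 (adjusted p = 1.48e-28). Lower in stamen too were the YABBY gene YAB6 (LOC4352818, -8.19 ± 0.36), the silicon transporter family gene NIP2-2 (LOC4340558, -8.09 ± 0.33), the metal transporter gene NRAMP5 (LOC4342859, -7.36 ± 0.34) and the MADS gene MADS15 (LOC4342214, -7.38 ± 0.22). Of the floral MADS genes 8 rose, 7 fell and 2 did not pass (15 adjusted over the list alone, camera adjusted p = 0.911). The stamen identity gene MADS3 (LOC9271572, 5.26 ± 0.22) was higher in stamen, and MADS1 (-4.53 ± 0.32) in palea and lemma.

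Of 8 tapetum and pollen wall genes in stamen 6 rose, 0 fell and 2 did not pass (6 adjusted over the list alone, camera adjusted p = 0.000207, adjusted p = 0.00589 with an estimated correlation), with GAMYB (LOC4327362, 4.40 ± 0.22) and TDR (3.82 ± 0.19). In the mature pollen list 2 rose, 0 fell and 0 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0156, adjusted p = 0.0653 with an estimated correlation). For photosystem and antenna genes 1 rose, 8 fell and 0 did not pass (9 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.246 with an estimated correlation), for example PSAH (-4.94 ± 0.41) and CAB2R (-4.72 ± 0.59). In the secondary wall list 0 rose, 13 fell and 11 did not pass (13 adjusted over the list alone, camera adjusted p = 0.0156, adjusted p = 0.228 with an estimated correlation), with BC1 (-7.15 ± 0.43), LAC10 (LOC4332400, -6.91 ± 0.45) and CESA4 (-6.64 ± 0.41). In stamen 5938 probe sets were higher and 8654 lower, but without a minimum difference 16241 and 12353. In 5755 probe sets the difference was itself unequal between the varieties, whose stamen arrays also differed in RNA quality, as given below. In stamen the 3′ minus 5′ signal was 1.01 ± 0.345, against 1.39 ± 0.496 (SD, n = 4) in palea and lemma.

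Endosperm was followed at 7, 14 and 21 days after pollination, and day 14 was set against day 7 first (n = 4 and 4). The alpha-amylase gene AMY1.2 (LOC4347262) rose by 6.42 ± 0.53 (adjusted p = 4.12e-18, range 5.24 to 7.60), and so did PM1 (4.46 ± 0.59) and the dehydrin gene RAB16C (4.32 ± 0.65). For AMY1.2 the day 14 samples lay far apart (7.98 and 12.69 in Minghui 63, 11.78 and 7.70 in Zhenshan 97). The isocitrate lyase gene ICL (5.22 ± 0.59) and the chitinase gene Cht-1 (LOC4342115, 4.67 ± 0.48) rose too. The lipid transfer protein gene LTP110-A (LOC4349601) fell by 6.53 ± 0.39 (adjusted p = 2.24e-26), and so did the expansin gene EXPB3 (LOC4349349, -5.61 ± 0.49, range -6.25 to -4.97) and the sucrose synthase gene RSUS3 (LOC4343910, -3.96 ± 0.24). Of 9 LEA and dehydrin genes 5 rose, 1 fell and 3 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0204, adjusted p = 0.369 with an estimated correlation). Among cell cycle and replication genes 1 rose, 14 fell and 7 did not pass (15 adjusted over the list alone, camera adjusted p = 0.000168, adjusted p = 0.365 with an estimated correlation). The replication licensing genes MCM5 (LOC4331016, -3.65 ± 0.45, range -4.56 to -2.74), MCM2 (LOC4350526, -3.60 ± 0.42, range -4.62 to -2.59) and MCM4 (LOC107275673, -3.45 ± 0.44, range -4.35 to -2.55) were the larger falls. Of the heat shock genes 12 rose, 1 fell and 32 did not pass (14 adjusted over the list alone, camera adjusted p = 0.00167, adjusted p = 0.365 with an estimated correlation), with HSP18.6 (LOC4330933, 4.00 ± 0.60) and HSFC2A (LOC4328809, 3.67 ± 0.54).

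Of 13 starch synthesis genes by day 14, 0 rose, 4 fell and 9 did not pass (4 adjusted over the list alone, camera adjusted p = 0.109), with RSUS2 (LOC4340386, -1.54 ± 0.18). None passed of 10 seed storage protein genes (0 adjusted over the list alone, camera adjusted p = 0.289) or 5 core histone genes (0 adjusted over the list alone, camera adjusted p = 0.143). The counts were 2647 higher and 3709 lower. The 3′ minus 5′ signal was 1.2 ± 0.193 at day 14 and 0.785 ± 0.305 (SD, n = 4) at day 7.

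From day 14 to day 21 (n = 4 and 4) the alpha-amylase gene AMY1.4 (LOC4345812) rose by 4.55 ± 0.54 (23.5-fold, adjusted p = 6.08e-11, range 3.24 to 5.86), and so did OC-X (LOC4335551, 3.88 ± 0.50). The sucrose transporter gene SWEET11 fell by 6.62 ± 0.63 (adjusted p = 8.85e-15, range -8.65 to -4.59), and so did the MADS gene MADS7 (-5.78 ± 0.41, range -7.15 to -4.40) and the auxin-conjugating enzyme gene GH3.4 (-4.90 ± 0.48, range -6.26 to -3.54). At day 21 SWEET11 read 3.47, 3.74 and 4.62 in 3 samples and 11.58 in replicate 2 of Minghui 63. Of the starch synthesis genes 1 rose, 5 fell and 7 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00203, adjusted p = 0.0433 with an estimated correlation), with the sucrose synthase genes RSUS2 (-2.32 ± 0.18) and SUS5 (LOC4335447, -1.79 ± 0.36). Of the seed storage protein genes 0 rose, 1 fell and 9 did not pass (1 adjusted over the list alone, camera adjusted p = 0.0617). In the LEA and dehydrin list 1 rose, 0 fell and 8 did not pass (1 adjusted over the list alone, camera adjusted p = 0.635), the rise being RAB16D (3.40 ± 0.64). Heat shock genes went both ways, as 7 rose, 2 fell and 36 did not pass (9 adjusted over the list alone, camera adjusted p = 0.0617), with HSFA2A (LOC4334080, 2.64 ± 0.51) and HSP22.3 (LOC4339231, -2.60 ± 0.28). The counts were 3361 higher and 2337 lower.

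**Figure D4:**
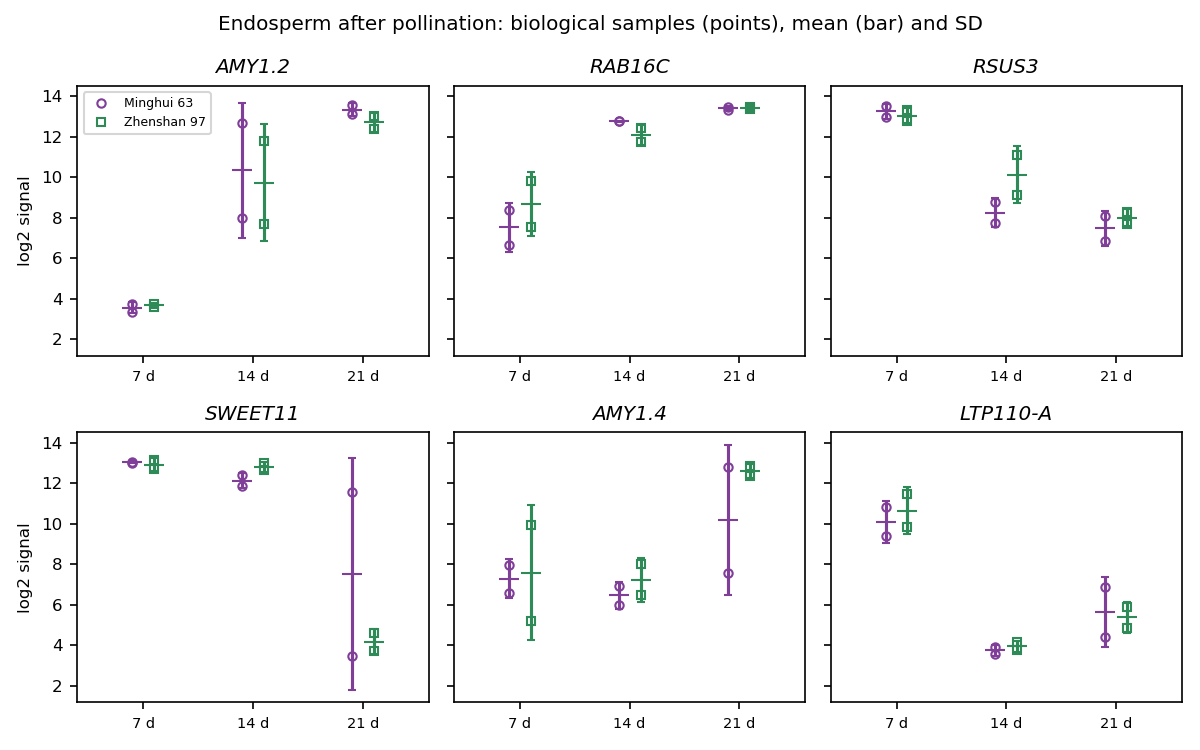
Log2 signal (vertical axis) of 6 genes in endosperm 7, 14 and 21 days after pollination (horizontal axis), with points for samples and mean and SD by variety. The samples of Minghui 63 at day 21 lie far apart for SWEET11 and AMY1.4, and those of both varieties at day 14 for AMY1.2.

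Organ-preferential probe sets were at least 2 above each of the other 8 organ classes in both varieties. Of 160 samples 102 had a class, and radicles counted as root. Callus around infection, older panicles, spikelets, germinating seed, seedlings, plumules and shoots had none. Endosperm had 375, among them the glutelin genes GLUA-1 (LOC4327027, 12.8 ± 0.41 SD, 4.06 in callus) and GLUB-5 (13.3 ± 0.39 SD, 5.28 in callus). Stamen had 1081, with SPPL3 (11.3 ± 0.55 SD, 5.16 in palea/lemma) and RTS (10.8 ± 0.79 SD, 4.84 in palea/lemma). Root had 274, with TIP2 (12.5 ± 0.14 SD, 4.90 in callus) and NAS1 (11.9 ± 1.0 SD, 4.39 in callus), and callus 124, with AMY1.1 (12.4 ± 0.88 SD, 4.40 in endosperm) and the oxygen-binding globin gene NSHB2 (13.1 ± 0.37 SD, 8.00 in root). Young panicle, whose samples were all read on technical arrays, had 232, with APO2 (9.77 ± 1.4 SD, 4.65 in stamen) and LAX1 (8.95 ± 1.4 SD, 4.69 in root). Palea and lemma had 47, with Cht5 (LOC4336265, 10.5 ± 0.40 SD, 6.63 in sheath), leaf blade 68, stem 25, with CCD8A (LOC4327933, 8.52 ± 0.37 SD, 5.63 in sheath), and sheath 19. The total was 2245.

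The varieties were compared over the 36 shared tissues. Averaged over these, 468 probe sets were higher and 483 lower in Minghui 63 (7965 and 6823 without a minimum difference), and 508 of the 951 had the same sign in every tissue. Named genes of this kind were few. Higher in Minghui 63 were the Dicer-like gene DCL2A (LOC4333337, 1.78 ± 0.066), SDH3-2 (LOC4343404, 1.08 ± 0.043) and DAHPS2 (LOC4343946, 1.02 ± 0.033), with adjusted p of 2.07e-42, 3.04e-40 and 1.2e-46. Higher in Zhenshan 97 were PMEI28 (LOC4344463, -2.57 ± 0.092), GUT1 (LOC4348204, -2.33 ± 0.068), SPO11-4 (LOC4352826, -2.32 ± 0.071) and the cell cycle inhibitor gene KRP6 (LOC4347280, -1.25 ± 0.10). Within single tissues between 898 (shoot) and 7073 (stamen) probe sets passed, with a median of 1403. The stamen arrays of Minghui 63 had 14.68% and 15.88% of values above 8, against 17.49% and 17.3% in Zhenshan 97. Their 3′ minus 5′ signals were 0.733 and 0.687, against 1.31 and 1.3. For leaf 2 in the labels Minghui 63 had 2.42 and 2.55, and Zhenshan 97 0.998 and 1.06. Variety and RNA quality are not separated in these tissues or some others. Of 21618 that passed in 1 or more tissues, 10162 did so in exactly 1, 50 were higher in Minghui 63 in all 36 tissues and 52 higher in Zhenshan 97. Where the genes with constant differences had other bright probe sets, 37 of 99 passed the same way.

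**Figure D5:**
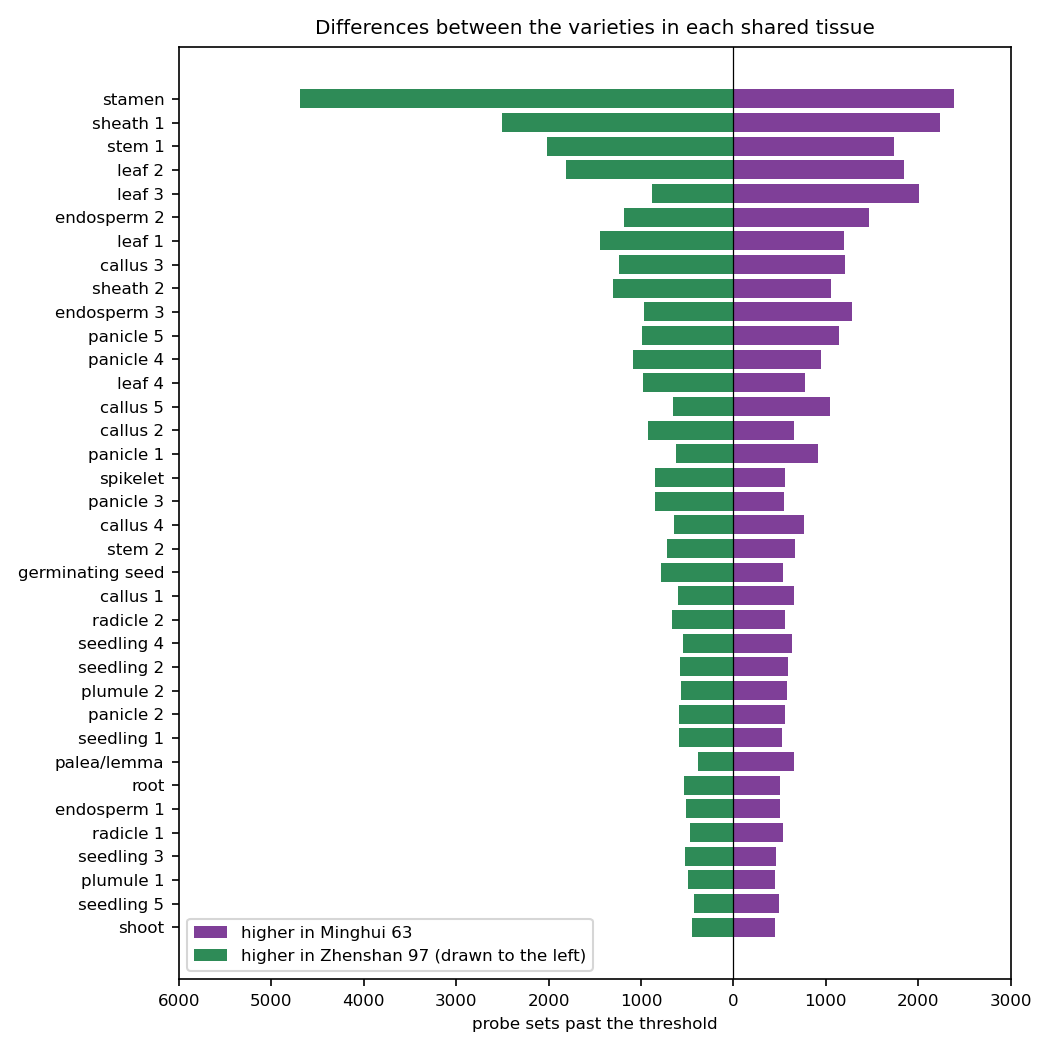
Number of probe sets (horizontal axis) past the threshold between the varieties in each shared tissue (vertical axis, named as in the labels), higher in Minghui 63 to the right and in Zhenshan 97 to the left. Stamen has the longest bar on each side, and shoot has the lowest sum of both bars.

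Of the 104 list tests, camera called 46, and 19 of these calls held with an estimated correlation. Held calls were the photosystem, Calvin cycle, chlorophyll and clock lists in lit plumules, the photosystem and cytokinin lists in regenerating callus, and the jasmonate pathway at both times after infection. They further took in the photosystem and nutrient transport lists in root, the wall and expansin lists in sheath, and the MADS, meristem and tapetum lists in panicles of 10 to 15 mm. The last were the pollen and meiosis lists at heading, the tapetum list in stamen and the starch list at day 21. Of these calls 4, and of the held ones 2, belong to the lists of mature pollen families (2 genes) and the Calvin cycle (4 genes). Both lie below the 5 members asked of lists tested elsewhere.

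The median, the mean and the camera direction of a list did not all share a sign in some tests, none of them called by camera. Fry called 2 of these, floral MADS genes in stamen (adjusted p = 2.29e-05) and the auxin response with KT (adjusted p = 0.0412). In callus these were defence proteins with subculture and at the screening stage, cell cycle genes at the screening stage, and glutathione transferases 1 h after infection. In seedlings they were expansins in plumules, cytokinin response with NAA, auxin response and clock genes with GA3, auxin response and the jasmonate pathway with KT, and cell cycle genes at the trefoil stage. The others were secondary wall genes in root, meiosis genes in panicles of 10 to 15 mm and floral MADS genes in stamen, where the median was -0.76 and the mean -0.36 beside an upward camera direction.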

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

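Both tests of the reporter probe set, the test with different sample numbers, the range of array-set differences within a set and the count of splits without the one that parts the varieties were chosen only after the result was seen. A reporter control probe set, outside the rice genes, was 9.24 higher in the 8 samples of screening-stage and regenerating callus than in the other 152. It read 11.55 to 12.99 there, against a median of 3.14 and a maximum of 4.94 elsewhere. The other 63 reporter probe sets had a median difference of -0.0621 (quartiles -0.0866 to 0.0014, largest 0.309), which argues against brighter controls on these arrays. Infected and uninfected callus differed by 0.0692, so infection gave no such signal by 6 h, but later carry-over was not tested. A transgene introduced before the screening stage is another untested candidate.

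The response shared by the 3 hormone groups had a median of 1.4 over 2508 probe sets. Splitting the untreated samples between hormones kept at least 75.3% of the shared number, which argues against shared control samples as the whole cause. Same-numbered treated samples resembled each other across hormones, but different numbers with split controls kept at least 52.1%, which argues against this likeness as the whole cause. The array set of the untreated seedlings remains open: the same probe sets moved by 0.514 in panicles (quartiles 0.116 to 0.963, 80.9% the same way), which decides nothing. Between plumules and 3-day seedlings they moved by 0.989 (85.4% the same way), which goes with the array set, but tissue differs there too. Within 1 set the same median ran from -0.48 to 0.365 over 18 comparisons, and a hormone response stays possible and was not tested apart from the set.

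Probe sets with 1 direction between the varieties in every tissue could reflect sequence differences under single probe sets. Among 99 bright partner probe sets of the same genes 37 passed the same way, or 37.4% (95% exact interval 27.9 to 47.7), and 2 the opposite way, against 2.66% of probe sets of such genes in general. This lies between the bounds set for either answer, so probe sequence and expression cannot be told apart for these genes. A difference in expression between the varieties stays open and untested.

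First in each sentence below is the number of probe sets whose difference was itself unequal between the varieties, by a test of that difference. After it come the real count with the compared samples alone and the highest count among other splits of these samples. In most comparisons the real split alone reached its count. This lowest possible share (1 of 35 splits, or 1 of 100 for the hormones, trefoil, sheath and young panicles) does not exclude chance. In each comparison with 35 splits the highest other split parts the varieties, a contrast of its own. Light in the plumule gave 37, and 2080 against 734. Induction at 31 degrees gave 359, and 2864 against 936. Subculture gave 926, and 5621 against 661. The screening stage gave 228, and 3105 against 1313. Regeneration gave 240, and 1944 against 981. NAA gave 66, and 3538 against 813. GA3 gave 75, and 3201 against 586. KT gave 44, and 3594 against 686. The trefoil stage gave 98, and 2590 against 971. Root against shoot gave 214, and 8368 against 422. Sheath against blade gave 920, and 3086 against 1. Young panicles gave 830, and 1415 against 409. The heading panicle gave 1004, and 10653 against 668. Stamen gave 5755, and 14150 against 8. Endosperm day 14 gave 657, and 5602 against 405. Endosperm day 21 gave 580, and 4811 against 571. The flag leaf gave 1213, and 4161 against 700. The stem gave 2138, and 2936 against 733. For light in the radicle there were 148, and 5 against 889, with 2 of 35 splits as large. The larger one parts the varieties, and without it 1 of 34 was as large, so the outcome depends on counting that split. The light response of plumule against radicle gave 1686, and 1308 against 10346. With 3 of 100 splits as large, chance was not excluded. The highest split called several times the real count, and the cause was not tested. For the mean of the varieties the values were 945 against 0 (1 of 100 splits), and for the organ classes 2208 against 0 (1 of 30). The same limits apply to both.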

How the results depend on the processing

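No minimum difference, the block in the hormone contrast and the removal by 3′ minus 5′ signal were chosen only after the data were seen. Centring on array medians, renewed quantile normalization, array weights and the variance model with trend kept all 24 counts within 1.5 times, and the first technical array all 7 it applied to. Without dim probe sets all 25 results stayed within that factor. With only the compared groups 23 of 24 did, with a replicate block as well 21 of 23. Named calls were weaker in 26 cases, and in 38 with the block. Without samples of a high 3′ minus 5′ signal all 5 counts that lost samples did (4104 for GA3, 9136 for root, 5559 for sheath, 10581 for the heading panicle and 14510 for stamen). Subcultured and screening-stage callus could not be run so, and the block could not be fitted for the varieties. Array weights of 5 fits stopped before their tolerance was reached.

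Without a minimum difference, which by construction lets smaller differences pass, the counts, with those higher in brackets, were plumule 4475 (2819), 31 degree callus 6248 (3136), subcultured callus 12917 (7177), screening-stage callus 8691 (4115), regenerating callus 3849 (2241), Agrobacterium at 1 h with 10362 (4175), NAA 20695 (8924), GA3 19559 (8568), KT 17482 (9618), trefoil 13712 (8566), root 17885 (10549), sheath 13572 (5715), young panicle 4381 (2274), heading panicle 19362 (7745), stamen 28594 (16241), endosperm at day 14 with 15158 (7272) and at day 21 with 17153 (8700), flag leaf 11257 (5765), stem 11198 (5032) and varieties 14788 (7965). With 1 probe set per gene, which tests fewer probe sets, they were radicle 232, 31 degree callus 1644, subcultured callus 3135, screening-stage callus 1360, Agrobacterium at 1 h with 4092 and at 6 h with 3465, NAA 1599, GA3 1574, KT 1647, trefoil 1568, root 5310, sheath 2378, young panicle 917, heading panicle 6467, stamen 8465, endosperm at day 14 with 3881 and at day 21 with 3328, flag leaf 3419, stem 3258, varieties 356 and organ classes 1096. Organ classes gave 1206 with a minimum of 3, and the varieties 443 without probe sets of 1 direction in every tissue, both by construction lower. With only the compared groups the radicle gave 64, and with a replicate block as well 6, while the flag leaf gave 3290, and the cause was not tested. Against the mean of the other hormones NAA gave 1, GA3 0 and KT 3 probe sets, and with the block 6, 0 and 24. In limma 3036 probe sets for GA3 had an unadjusted p under 0.05 with the block and 1001 without it. Of 46 called lists 19 stayed called with an estimated correlation, and fry called 56, of which 42 were shared.

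Named values of opposite sign against the other hormones were, with NAA, MRL7 -0.089, GYRA -0.029, BGLU3 -0.047, EGY1 -0.11, CHLG -0.038, AL1 -0.076, PT1 -0.22, RAB16D 0.22, MADS18 0.039, Cht1 0.52, CIPK5 0.29 and CM-LOX1 -0.58. With GA3 they were MRL7 -0.014, RAB16D 0.46, MADS18 0.29 and Cht1 0.16, and with KT GH3.2 -0.57. These values were alike with the block. Fry turned the direction of the auxin response with KT (median 0.184, adjusted p = 0.0412) and of floral MADS genes in stamen (median -0.759, adjusted p = 2.29e-05), and neither cause was tested. Leaving out each sample in turn, a lone sample being assumed to vary like the other groups, gave 3375 to 4223 for Agrobacterium 6 h (lowest without replicate 1 at 6 h). It gave 244 to 443 for the radicle (lowest without light-grown Zhenshan 97 replicate 2) and 1107 to 2324 for the light response (lowest without dark-grown plumule Zhenshan 97 replicate 2). The other counts stayed within 1.5 times. Of 374 named genes and comparisons, 49 lost their call without some sample, and for 76 the fold moved by more than 1.5 times. Of 3444 genes with several probe sets, up to 45 per comparison had opposite calls. Signal near the background limits what dim probe sets can show.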

Other observations

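The list tests in this part, outside those fixed for a comparison, were all chosen only after the results were seen. In callus at 31 degrees, of 16 diterpenoid phytoalexin genes 0 rose, 12 fell and 4 did not pass, with a median of -2.44 (12 adjusted over the list alone, camera adjusted p = 4.02e-12, adjusted p = 0.0486 with an estimated correlation), where the 3′ minus 5′ signal lay 0.289 lower. In subcultured callus, of 10 seed storage protein genes 1 rose, 7 fell and 2 did not pass, with a median of -5.58 (8 adjusted over the list alone, camera adjusted p = 5.55e-11, adjusted p = 0.0408 with an estimated correlation), where the 3′ minus 5′ signal lay 1.26 higher. Of chlorophyll synthesis genes in root against shoot, 0 rose, 15 fell and 1 did not pass, with a median of -3.09 (15 adjusted over the list alone, camera adjusted p = 1.32e-10, adjusted p = 0.00445 with an estimated correlation). Of photosystem and antenna genes in panicles of 10 to 15 mm, 5 rose, 0 fell and 4 did not pass, with a median of 2.24 (5 adjusted over the list alone, camera adjusted p = 1e-08, adjusted p = 0.0375 with an estimated correlation).

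Of defence protein genes in the heading panicle, 12 rose, 0 fell and 5 did not pass, with a median of 3.10 (12 adjusted over the list alone, camera adjusted p = 8.88e-06, adjusted p = 0.0304 with an estimated correlation). Of floral MADS genes from day 14 to day 21 of the endosperm, 0 rose, 12 fell and 5 did not pass, with a median of -1.26 (12 adjusted over the list alone, camera adjusted p = 1.13e-13, adjusted p = 0.000558 with an estimated correlation). In the older flag leaf, of jasmonate pathway genes, 19 rose, 0 fell and 13 did not pass, with a median of 1.23 (19 adjusted over the list alone, camera adjusted p = 5.05e-09, adjusted p = 0.0473 with an estimated correlation). Of its chlorophyll synthesis genes, 0 rose, 9 fell and 7 did not pass, with a median of -1.24 (10 adjusted over the list alone, camera adjusted p = 1.85e-06, adjusted p = 0.0473 with an estimated correlation).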
